A study of Mus musculus with 61 samples.

How the data were processed

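Gene counts of 61 mouse RNA-seq libraries in 22 groups were analysed: 17 libraries of sorted cells and 44 of whole tissue (30 of skin and 14 of ear). Per the labels' protocols, 1000 double-sorted cells per library went into lysis buffer, whole tissue was extracted with Trizol, and cDNA made from an oligo(dT) primer was amplified, fragmented with Tn5 and sequenced as paired ends of 38 bases. Imiquimod cream (125 µg at 5%) was put on both sides of the ear until the stated day. The deposited values are raw counts per gene for 55011 genes, made with STAR 2.7.3a on mm10 and featureCounts per the submitters' processing notes. The strand setting and the gene annotation behind the counts were not given in the sources used here, so counts of overlapping or nearly identical genes are uncertain. Gene positions and types were read from GENCODE mouse release 21, which gave a type to 53009 of the genes.

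Samples were grouped by the labels. Among the count columns 12 are named 8w although the labels of those samples say 10 weeks, and the labels were followed. These are the 6 untreated ear libraries and replicates 1 to 3 of each genotype of 10-week skin. Another 12 columns carry numbers that differ from the numbers in the titles of their groups. They were matched to the labels by group only, and their libraries are called a and b here. No pair of libraries was identical, and the 62 pairs of replicates were checked for libraries closer to each other than sampling allows. None was, and the closest pair, control ear on day 3, had a chi-square per degree of freedom of 1.211. As 1 of the 2 held 4059 counts, they were summed as a cautious choice.

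The tests ran in R 4.3.3 with edgeR 4.0.16: TMM normalisation, the filterByExpr filter by group, a robust quasi-likelihood fit (glmQLFit and glmQLFTest) and Benjamini-Hochberg adjustment, with a gene called at an adjusted p under 0.05. Log2 changes carry the prior count of 0.125 and their SE. Each sorted comparison had its own fit (10794 genes for spleen Treg cells, 12731 for Tcon cells, 12711 for γδ T cells and 12522 for γδ T against Tcon cells). The 43 whole tissue samples in 16 groups shared 1 fit of 30890 genes with 27 residual degrees of freedom, and contrasts between group means gave the comparison at each age and treatment, the mean over ages, the genotype by age test, the imiquimod effects and their interaction with genotype. A lone sample in a group is assumed to vary like the other groups. CPM values are TMM-normalised and shown as mean ± SD. Izumo1r was also tested by exact permutation of mean log2 CPM.

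The libraries were compared over 39 gene lists written before the data were examined, as were the comparisons, the tests and the rule for naming genes. Each list with at least 5 tested members was tested with camera (limma 3.58.1, statmod 1.5.0) at the preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Members were counted from the edgeR p-values adjusted over all genes and over the list alone. Where a group has 0 counts, the fold is a lower bound against 3 counts over the group.

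Genes were named by rule. Izumo1r is named in each sorted comparison. In a comparison of groups, the 10 largest rises and 10 largest falls are named among genes called, with a mean log2 CPM of at least 3 and no overlap between the groups' libraries, leaving out predicted and clone names, rearranging immunoglobulin and T cell receptor segments, mitochondrial genes, Y-linked genes and Xist. For interaction and averaged contrasts the overlap condition was dropped, for tests over several groups the 10 smallest p-values were taken, and where no gene passed the 3 smallest p-values in each direction are given as values. The text names the first 5 in each direction outside the genotype comparisons and day 3 of imiquimod in control ear. Up to 4 members per list were taken by smallest p, and fixed marker genes were read in all groups.

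Power was tested on simulated data with 200 genes changed, by 2-fold or 4-fold, and a list of 20 genes, in the comparisons named next and in γδ T against Tcon cells. Skin at 2 and 4 weeks, the mean over ages and the interactions were not simulated. Of genes changed 4-fold, 89% were recovered in spleen Treg cells, 96% in Tcon cells, 11% in γδ T cells, 11% in skin at 1 week, 1% at 8 weeks, 50% at 10 weeks, 14% in untreated ear and 0% on day 1 and day 3 of imiquimod. Of genes changed 2-fold, 69% and 37% were recovered in Treg and Tcon cells and at most 1% in γδ T cells and the whole tissue comparisons simulated. False calls were at most 8.3% of simulated calls, and the simulated list was called in each of these apart from day 3 (adjusted p = 0.0808). Other splits of the real untreated ear libraries called up to 35 genes, so this share may not hold for real libraries.

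Alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, no low-count filter, fits of only the libraries compared, the replicate number as a block, leaving out each replicate in turn, a minimum of 2-fold, an additive model for the mean over ages, subsets of the 10-week libraries, and their set (libraries a and b, or replicates 1 to 3) as a covariate. After the data were seen, 2 more were added: the day 3 control libraries kept apart, and a fit without libraries that had under 100000 counts or over 20000 genes seen at 500000 counts. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.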

Results

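The study removed Izumo1r (folate receptor 4, a surface protein abundant on regulatory T cells) from cells that express Foxp3, the transcription factor that defines regulatory T (Treg) cells, by crossing mice with a floxed Izumo1r gene to mice whose Cre recombinase is driven by Foxp3. Control mice carried the Foxp3-driven Cre without the floxed gene, and all were on the C57BL/6 background. RNA was sequenced from 61 libraries in 22 groups. Treg cells were sorted from the spleen at 8 weeks (n = 3 per genotype). From skin at 10 weeks came conventional CD4 T (Tcon) cells, gated as TCRβ-positive, CD4-positive and negative for the Foxp3 reporter (n = 3 per genotype), and γδ T cells, gated as γδTCR-positive, TCRβ-negative and CD19-negative (n = 3 control and 2 knockout). Whole skin was taken at 1 week (n = 3 per genotype), 2 weeks (n = 2), 4 weeks (n = 3), 8 weeks (n = 2) and 10 weeks (n = 5). Whole ear was taken at 10 weeks without treatment (n = 3 per genotype) and on day 1 (n = 2) and day 3 of 5% imiquimod cream, which activates Toll-like receptor 7 and gives a psoriasis-like inflammation.

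The sorted libraries held 2195976 to 8199661 counts. Whole tissue held 728988 to 8629011 counts, apart from 17351 in knockout skin a at 2 weeks and 4059 in control ear replicate 1 on day 3. The latter differed from replicate 2 of its group by about the sampling noise (chi-square per degree of freedom 0.989 over 564 genes, against 2.5 to 22.18 for 42 libraries of other groups). Replicates of other groups thinned to 4059 counts gave 0.884 to 170.5 (median 2.364, 88 pairs, 1 of them at or below the value seen), so separate replicates can also lie this close. The data do not show that the 2 are 1 sample. As the cautious choice both were summed, so control ear on day 3 had n = 1 and knockout ear n = 2. The count columns of untreated ear and of 10-week skin replicates 1 to 3 are named 8w although the labels say 10 weeks, so a difference in age between untreated and treated ear, or within 10-week skin, cannot be excluded. The sex of the mice differs within some groups of whole skin by Xist and Ddx3y, and no model holds it. Whether the libraries of a group came from separate animals was not given in the sources used here, so the p-values measure the spread between these samples. Values below are TMM-normalised CPM (counts scaled to library size) as mean ± SD and log2 changes (knockout minus control, unless stated) ± SE.

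Izumo1r lies on the minus strand of chromosome 9 from 14885814 to 14903949 (mm10). In spleen Treg cells it had 1540 ± 91.3 CPM in controls, with libraries between 1450 and 1630, and 264 ± 10.2 CPM in knockouts, with libraries between 257 and 276 (log2 change -2.54 ± 0.09, adjusted p = 5.69e-12). In skin Tcon cells the control libraries held 61.1 to 122 CPM and the knockout libraries 14.0 to 20.1 CPM. An exact two-sided permutation test of each of these 2 comparisons gave p = 0.1, the smallest that 3 against 3 samples allow. In γδ T cells Izumo1r had 2 counts over the 3 control libraries and 0 over the 2 knockout libraries. In whole skin and ear no group held more than 28 counts, and those 28 all came from untreated control ear replicate 1, so Izumo1r gives no check of the tissue labels. Which exons are floxed, and so which part of the transcript the remaining counts come from, was not given in the sources used here.

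**Figure D1:**
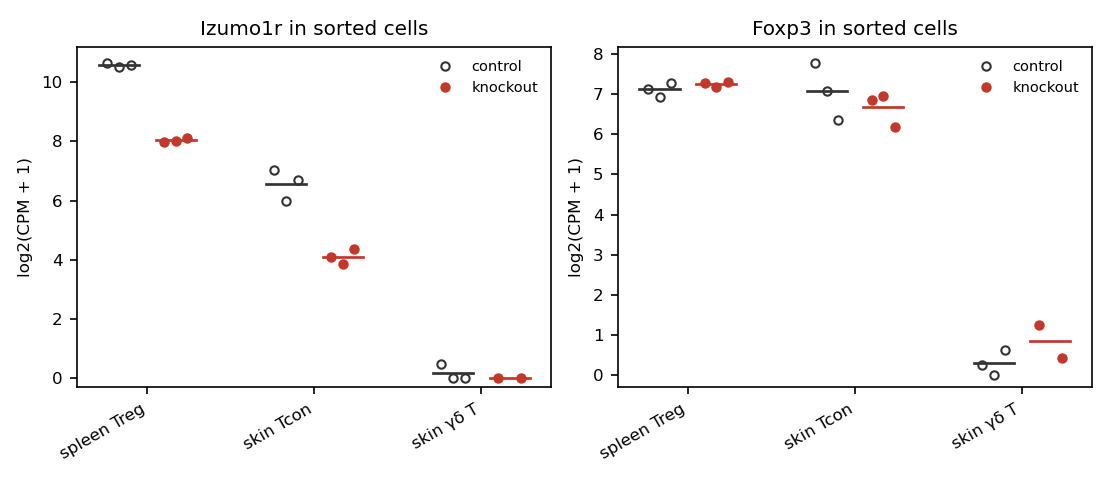
Izumo1r (left) and Foxp3 (right) as log2(CPM + 1) in the sorted cells of each genotype, with 1 point per library and a line at the group mean. Izumo1r is lower in every knockout library than in every control library of spleen Treg and skin Tcon cells, and Foxp3 is detected at similar levels in those 2 populations but at under 2 CPM in γδ T cells.

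Spleen Treg cells were compared to ask what changes in Treg cells that lose Izumo1r (n = 3 per genotype). Apart from Izumo1r, the largest falls were in Tysnd1 (a peroxisomal protease), from 27.1 ± 9.91 to 4.83 ± 1.75 CPM (log2 -2.48 ± 0.42, adjusted p = 0.00772), Tmem62 (-2.35 ± 0.35), Rrad (-2.09 ± 0.36) and Trp53rka (-1.96 ± 0.44). Dnajb11 and Sdf2l1, which act in protein folding in the endoplasmic reticulum, fell by 2.10 ± 0.35 and 2.03 ± 0.33 on the log2 scale (adjusted p = 0.0226 and 0.00601). Rrs1 (ribosome assembly), B3galt6 (glycosaminoglycan synthesis) and Rab6a (Golgi transport) fell by 1.98 ± 0.40, 1.92 ± 0.31 and 1.89 ± 0.35. The largest rises were in Fntb, a subunit of farnesyltransferase (log2 1.93 ± 0.38, 32.5 ± 9.71 against 8.57 ± 4.00 CPM), and Churc1 (1.55 ± 0.22), whose annotated spans overlap on the same strand of chromosome 12, so their counts cannot be separated with certainty. Sdc4 (syndecan-4) rose from 31.1 ± 4.80 to 82.8 ± 8.85 CPM (1.41 ± 0.20, adjusted p = 0.00281), and Tspan13 from 214 ± 17 to 399 ± 71.7 CPM (0.89 ± 0.12, adjusted p = 0.00242). Vmn2r97 (1.20 ± 0.24), Ifit1bl1 (1.08 ± 0.19), Ppp1r16b (1.06 ± 0.17), Dipk1a (0.85 ± 0.18), Znrf3, a ubiquitin ligase that lowers Wnt signalling (0.66 ± 0.14), and Pdcd4, an inhibitor of translation (0.49 ± 0.10), also rose.

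In all, 73 of 10794 genes passed edgeR's test in spleen Treg cells, 13 higher and 60 lower in the knockout (165 by DESeq2). Foxp3 was 153 ± 5.92 CPM in knockout and 139 ± 18.4 CPM in control cells (adjusted p = 0.849). The list of T cell receptor response genes fell (adjusted p = 1.72e-05, and adjusted p = 0.542 with an estimated correlation), with 4 of 20 members lower when adjusted over the list alone and 0 over all genes. The phosphatase Dusp2 had 19.5 ± 5.14 CPM in knockout and 61.1 ± 37.2 CPM in control cells, and the transcription factor Egr2 76.9 ± 29.1 and 146 ± 10.5 CPM. The effector and tissue Treg list fell as well (adjusted p = 0.000492, and adjusted p = 0.65 with an estimated correlation), with 2 of 19 members lower when adjusted over the list alone and 1 over all genes, the tumour necrosis factor receptor Tnfrsf1b (log2 -0.45 ± 0.10, adjusted p = 0.0421). Naive and central T cell genes rose (adjusted p = 1.72e-05, and adjusted p = 0.648 with an estimated correlation), 3 of 13 when adjusted over the list alone, with log2 values of 0.70 ± 0.19 for Igfbp4 and 0.40 ± 0.11 for the egress receptor S1pr1. Knockout replicate 3 lay among the controls on both of the last 2 lists, with a mean log2(CPM + 1) of 6.38 on the effector and tissue Treg list (controls 6.21 to 6.39, other knockouts 5.77 and 5.7) and 7.02 on the naive and central list (controls 6.88 to 7.02, other knockouts 7.38 and 7.31). Markers of cells outside the gate moved with the same genotype. The B cell list fell (adjusted p = 0.000492, and 1 of 9 members lower over the list alone; adjusted p = 0.542 with an estimated correlation), with Ighd at 15.1 ± 3.08 CPM in knockout and 31.1 ± 6.70 CPM in control cells. The dendritic cell list fell (adjusted p = 0.00872, and 0 of 9 members over the list alone; adjusted p = 0.65 with an estimated correlation). H2-Aa had 6.43 ± 6.93 and 62.1 ± 52.6 CPM. Without single libraries the count of 73 became 20 to 171, and the dendritic cell call ended without knockout replicate 3 (adjusted p = 0.13). Of the 20 named genes, 7 kept their call without each library in turn. Izumo1r, Churc1, Sdc4, Ifit1bl1, Tspan13, Tmem62 and Sdf2l1.

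Skin Tcon cells, which the sort selected as Foxp3 reporter-negative, were compared between the genotypes (n = 3 each). They held Foxp3 at the level of spleen Treg cells and lost Izumo1r to 16.7 percent of control, against 16.9 percent in spleen Treg cells, so they cannot be taken as cells outside the targeted population. Izumo1r was the only gene of 12731 to pass edgeR's test, against 1167 at an unadjusted p under 0.05 and 158 by DESeq2 (103 higher and 55 lower), from 95.3 ± 31.3 to 16.8 ± 3.04 CPM (log2 -2.50 ± 0.29, adjusted p = 0.0403). Genes of effector and tissue Treg cells rose as a list (adjusted p = 2.34e-16, and adjusted p = 0.228 with an estimated correlation), 11 of 20 members when adjusted over the list alone and 0 over all genes. The cytokine Il10 had 102 ± 30.5 CPM in knockout and 20.4 ± 7.64 CPM in control cells, and Klrg1 134 ± 32.0 and 52.4 ± 21.4 CPM. Type 17 T cell genes rose as a list (adjusted p = 7.26e-08, and adjusted p = 0.228 with an estimated correlation), 5 of 16 members over the list alone and 0 over all genes. Il17f had 33.4 ± 5.89 against 7.56 ± 1.73 CPM, Il22 32.3 ± 27.1 against 3.94 ± 3.28 CPM and Il17a 12.2 ± 6.64 against 4.88 ± 4.03 CPM. Naive and central T cell genes fell as a list (adjusted p = 1.91e-06, and adjusted p = 0.496 with an estimated correlation), 10 of 14 members lower and 1 higher over the list alone, with the transcription factor Lef1 at 62.8 ± 7.47 against 263 ± 200 CPM and Igfbp4 at 18.7 ± 9.14 against 341 ± 409 CPM. Control replicate 1 carries much of this gap: the list means were 7.95, 6.72 and 6 in controls 1, 2 and 3 and 5.04, 5.57 and 5.9 in the knockouts, and without it the median log2 change was -0.55 (adjusted p = 3.4e-05) in place of -1.27. Besides Izumo1r, which is a member and fell, 8 of the 16 Treg core genes rose over the list alone (list adjusted p = 2.51e-06, and adjusted p = 0.228 with an estimated correlation), with the IL-2 receptor Il2ra at 189 ± 39.9 against 74.8 ± 35.5 CPM and the checkpoint receptor Ctla4 at 806 ± 192 against 305 ± 167 CPM. T cell receptor response genes (adjusted p = 5.16e-11, 9 of 20 over the list alone), type 2 genes (adjusted p = 3.97e-07, 6 of 13) and glycolysis and hypoxia genes (adjusted p = 1.71e-06, 4 of 21 with 1 lower) rose as lists too, each at adjusted p = 0.228 with an estimated correlation. Of these, Nr4a3 had 493 ± 26.2 against 247 ± 43.3 CPM.

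Transcripts outside the gate were measured in the same Tcon libraries. Foxp3 had 107 ± 28.5 CPM in knockout and 140 ± 64.3 CPM in control cells (adjusted p = 0.764) although the sort excluded reporter-positive cells. Cd4 had 761 ± 104 and 808 ± 55.8 CPM, Cd8a 7.84 ± 7.63 and 1.70 ± 2.79 CPM, and Trdc 1.54 ± 1.32 and 8.96 ± 7.65 CPM. Ifng had 93.3 ± 18.4 and 65.9 ± 39.6 CPM and Gata3 1010 ± 347 and 685 ± 374 CPM. The call of Izumo1r in Tcon cells was lost without control replicate 1 (log2 -2.27, adjusted p = 0.257) and without knockout replicate 1 (-2.47, 0.121), 2 (-2.38, 0.458) or 3 (-2.64, 0.176), which left 0 genes each, while 22 genes passed without control replicate 3.

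In skin γδ T cells no gene of 12711 passed edgeR's test (n = 3 control and 2 knockout), against 1558 at an unadjusted p under 0.05 and 192 by DESeq2. The 3 smallest p-values on the higher side belonged to Sik1, a kinase of the salt-inducible family (754 ± 419 CPM in knockout and 89.2 ± 19.1 CPM in control cells), Tppp (107 ± 28.0 and 8.74 ± 4.66 CPM) and Dennd4a (1290 ± 459 and 177 ± 109 CPM), each at adjusted p = 0.241. On the lower side stood Lrrn4 (1.62 ± 1.37 and 31.3 ± 8.71 CPM), the proteasome assembly factor Psmd5 (10.6 ± 6.21 and 75.5 ± 22.3 CPM) and Tacc3 (2.31 ± 1.80 and 35.2 ± 20.4 CPM). Cytosolic ribosomal protein genes fell as a list (adjusted p = 9.85e-12, and adjusted p = 0.863 with an estimated correlation), with 0 of 38 members passing over the list alone and Rps5 at 892 ± 290 against 1970 ± 708 CPM. Knockout replicate 1 stood lowest (list mean 7.89, against 8.9 in replicate 2 and 9.26 to 9.37 in controls). Both knockout libraries were also lower on oxidative phosphorylation genes (6.48 and 6.94 against 7.36 to 8.11) and higher on fibroblast genes, markers of cells outside the gate (2.39 and 2.16 against 1.28 to 1.6). Proliferation genes fell as a list (adjusted p = 0.00217, and adjusted p = 0.863 with an estimated correlation), 1 of 27 members over the list alone. Aurkb, a mitotic kinase, had 0 counts in the knockout and 15.7 ± 9.57 CPM in control cells, at least 26.2-fold higher. T cell receptor response genes rose as a list (adjusted p = 0.0198, and adjusted p = 0.863 with an estimated correlation), 1 of 19 members over the list alone. Nr4a2 had 245 ± 53.7 against 55.1 ± 22.7 CPM. Rorc, the type 17 transcription factor, had 557 ± 4.67 and 564 ± 54.5 CPM, Il17a 77.2 ± 12.9 and 124 ± 128 CPM, Trdc 2150 ± 253 and 2010 ± 736 CPM, Trbc1 289 ± 96.6 and 453 ± 247 CPM, and Gata3 1180 ± 1440 and 231 ± 41.2 CPM. Without knockout replicate 2, which left 1 knockout sample whose spread is taken from the controls, 1528 genes passed. Without control replicate 1, 66 genes. The proliferation call ended without knockout replicate 2 (adjusted p = 0.128), and the T cell receptor call without control replicate 1 (0.0657) or knockout replicate 2 (0.684).

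Control γδ T and Tcon cells, both from skin at 10 weeks, were compared without pairing as a reference for both sorts (n = 3 each). Cd163l1 (scavenger receptor SCART1, a marker of IL-17-producing γδ T cells) had 6660 ± 851 CPM in γδ T and 0.892 ± 1.10 CPM in Tcon cells (log2 12.86 ± 0.79), followed by the kinase Blk (11.82 ± 0.54), the transcription factor Sox13 (11.62 ± 0.65) and the γ chain constant genes Trgc1 (10.12 ± 0.97) and Trgc4 (9.11 ± 0.65). Foxp3 (142 ± 65.2 CPM in Tcon cells, with 3 counts over the γδ libraries), Cd4 (log2 -9.04 ± 1.04), Ctla4 (-8.60 ± 0.64), Igfbp4 (-8.02 ± 1.3) and Cd28 (-7.76 ± 0.44) were lowest in γδ T cells. Izumo1r had 96.9 ± 31.7 CPM in Tcon cells and 2 counts in γδ T cells. In total 1315 of 12522 genes differed, 801 higher and 514 lower in γδ T cells. Type 17 genes were higher (18 of 20 members over all genes and over the list alone, adjusted p = 1.33e-23, and adjusted p = 0.0233 with an estimated correlation). Naive and central T cell genes were lower (11 of 14 over all genes and 12 over the list alone, with 1 higher, adjusted p = 2.51e-07, and adjusted p = 0.599 with an estimated correlation). Treg core genes were lower (9 of 15 over all genes and 10 over the list alone, with 3 higher, adjusted p = 0.00128, and adjusted p = 0.594 with an estimated correlation). The count fell as low as 749 without single libraries, and 20 of the 21 named genes, all but Igfbp4, kept their call without each library.

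Whole skin from 1 to 10 weeks asked when a difference between the genotypes appears. At 1, 2 and 4 weeks no gene of 30890 passed edgeR's test (535, 699 and 1228 at an unadjusted p under 0.05, and 13, 145 and 22 by DESeq2). At 2 weeks, however, a fit of only the libraries compared called 637 (86 higher, 551 lower), with library quality tied to genotype as given below. At 1 week (n = 3 per genotype) epidermal differentiation genes fell as a list (adjusted p = 4.72e-23, and adjusted p = 0.00472 with an estimated correlation) with 0 of 29 members passing over the list alone. With fry the list was not called (adjusted p = 0.0694). Its members went both ways, with Lce1g, a late cornified envelope gene, at 67.1 ± 31.2 against 146 ± 27.4 CPM and Krt1, a keratin of differentiating epidermis, at 2010 ± 1880 against 1090 ± 189 CPM. Interferon response genes rose as a list (adjusted p = 6.78e-08, and adjusted p = 0.167 with an estimated correlation; 0 of 32 over the list alone). Zbp1 had 7.93 ± 3.15 against 0.594 ± 0.612 CPM. The smallest p-values belonged to Tubgcp4 (28.1 ± 27.2 against 7.62 ± 0.537 CPM), Shoc2 (56.6 ± 49.4 against 18.7 ± 2.91), the collagen chaperone Serpinh1 (277 ± 209 against 79.2 ± 7.97), Hddc3 (2.7 ± 1.32 against 22.2 ± 4.81), Ecm1 (75.0 ± 29.7 against 169 ± 33.2) and Arrdc1 (32.7 ± 15.3 against 76.0 ± 16.1 CPM), all at adjusted p = 1.

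At 2 weeks (n = 2 per genotype) both controls are high-background and knockout library a has 17351 counts, so quality cannot be separated from genotype. Hair shaft and inner root sheath genes rose as a list (adjusted p = 1.21e-33, and 0.0288 with an estimated correlation), 0 of 30 members over the list alone. Padi3 had 438 ± 30.2 against 15.2 ± 15.5 CPM and Krt72 1800 ± 755 against 98.1 ± 108 CPM. Epidermal differentiation genes fell as a list (adjusted p = 6.27e-15, and adjusted p = 0.0234 with an estimated correlation), 9 of 29 over the list alone. Krt77 had 309 ± 263 against 2140 ± 435 CPM. Skeletal muscle genes, markers of another tissue, fell with them (adjusted p = 1.79e-12, and adjusted p = 0.162 with an estimated correlation), 19 of 22 over the list alone, with Tcap at 14.2 ± 20.1 against 201 ± 37.0 CPM. Single genes with the smallest p were Hras (610 ± 735 against 70 ± 4.22 CPM), Mab21l4 (256 ± 262 against 29.5 ± 13.5), Gpnmb (156 ± 196 against 12.7 ± 4.87), Gpd1 (9.47 ± 13.4 against 184 ± 132), the muscle calcium channel Ryr1 (20.8 ± 29.4 against 245 ± 80.7) and Myo18b (2.22 ± 3.14 against 43.4 ± 13.3 CPM), at adjusted p of 0.484 to 0.601. Without knockout library b, which left the shallow library alone, the hair call ended (adjusted p = 0.0539) and 5 genes passed. Without knockout library a the epidermal (0.12) and muscle (0.536) calls ended.

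At 4 weeks (n = 3 per genotype) Xdh, xanthine dehydrogenase, had 92.3 ± 37.5 against 17.4 ± 3.35 CPM (adjusted p = 0.187), Ndufs5 74.7 ± 50.7 against 6.21 ± 0.532 CPM, its processed copy Ndufs5-ps 4.16 ± 3.68 against 91.6 ± 7.82 CPM, and Atp1b1 59.6 ± 15 against 17.7 ± 7.25 CPM. Hddc3 had 2.19 ± 1.62 against 29.5 ± 5.08 CPM and Lmcd1 16.5 ± 3.32 against 51.5 ± 27.8 CPM. Proliferation genes fell as a list (adjusted p = 1.83e-08, and adjusted p = 0.176 with an estimated correlation; 0 of 27 over the list alone). Hmgb2 had 120 ± 59.2 against 187 ± 15.7 CPM. Knockout replicate 1 had a list mean of 4.81 and the other 2 lay among the controls (6.09 and 5.9 against 5.89 to 6.09), and without it the median log2 change was -0.21 in place of -0.37 (adjusted p = 4.34e-05). Without knockout replicate 1, 1 gene passed.

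**Figure D2:**
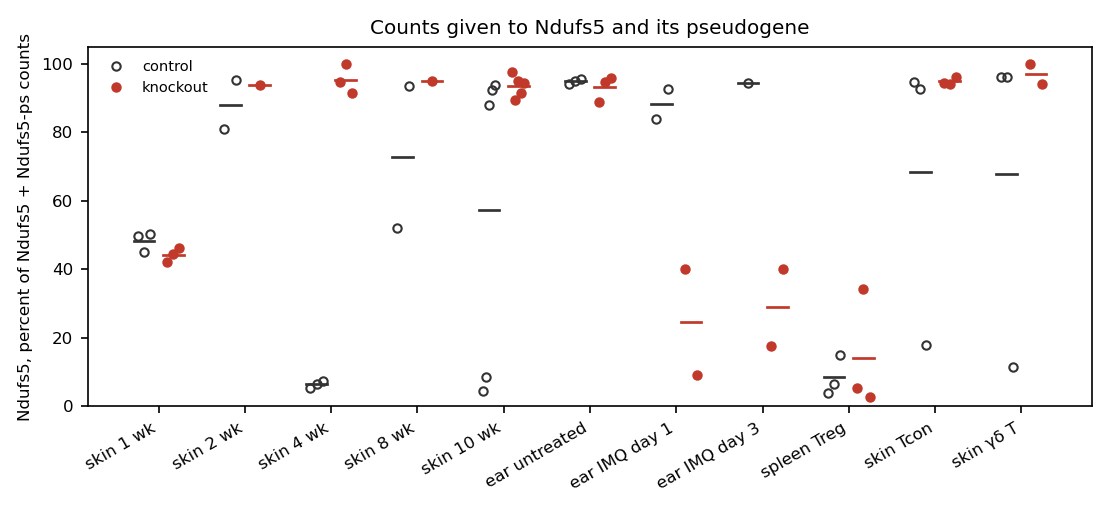
Percent of the joint counts of Ndufs5 and Ndufs5-ps that fall on Ndufs5 in 11 tissues and cell types by genotype, with 1 point per library and a line at the group mean. At 4 weeks control skin lies at 5.4 to 7.3 percent and knockout skin at 91.5 to 100 percent.

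At 8 weeks (n = 2 per genotype) 14 genes passed edgeR's test, 13 higher and 1 lower in the knockout, against 1564 by DESeq2 and 0 with only the libraries compared. The mitochondrial enzyme Gcat fell from 184 ± 174 to 14.0 ± 16.2 CPM (log2 -3.57 ± 0.68, adjusted p = 0.0101), and none of the 13 that rose met the rule for naming genes. Over all 30890 genes the median log2 change was 1.76 with TMM and 2.41 with DESeq2 size factors. Hair shaft and inner root sheath genes fell as a list (adjusted p = 8.6e-20, and adjusted p = 0.201 with an estimated correlation), 27 of 30 over the list alone and 0 over all genes. Krt72 had 0 counts in the knockout and 466 ± 658 CPM in control skin, at least 710-fold higher, and Foxn1, a regulator of hair growth, 2.78 ± 3.18 against 54.9 ± 53.7 CPM. Cytosolic ribosomal protein genes fell as a list (adjusted p = 2.07e-32, and adjusted p = 0.193 with an estimated correlation; 0 of 38 over the list alone). Rpl19 had 264 ± 181 against 596 ± 56.0 CPM. Most of this fall lies in knockout library b, a high-background library of 728988 counts (list mean 7.41, against 8.87 in knockout a and 9.68 and 9.18 in controls), without which the median log2 change was -0.53 in place of -1.16 (adjusted p = 1.68e-05). Without control library a the hair call ended (median log2 0, adjusted p = 0.187), Gcat was no longer called (-2.05, 0.564) and 0 genes passed. Without knockout library b Gcat was not called (-2.91, 0.615) and 0 genes passed. Without control library b and knockout library a the count was 39 and 610. Gcat had -6.95 without the latter.

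At 10 weeks (n = 5 per genotype) keratins and other genes of thickened, activated epidermis rose in knockout skin. Krt6b rose from 5.47 ± 5.74 to 168 ± 87.1 CPM (log2 4.92 ± 0.91, adjusted p = 0.0184), its partner Krt16 from 33.0 ± 34.0 to 568 ± 374 CPM (4.09 ± 0.80, adjusted p = 0.0261) and Krt6a from 90.4 ± 94.7 to 534 ± 264 CPM (2.56 ± 0.51, adjusted p = 0.0124). The cysteine protease inhibitors Stfa3 (4.27 ± 0.75) and Cstdc5 (4.05 ± 0.84) rose with them, as did Casp14, a protease of terminal differentiation (2.54 ± 0.41, adjusted p = 0.000602), and the glycerol channel Aqp3 (2.30 ± 0.43, 268 ± 163 against 54.7 ± 30.2 CPM). Wdr46 (2.98 ± 0.54), Gale (2.39 ± 0.51) and Nbeal2 (2.27 ± 0.45) also rose, and Prkag3, a muscle subunit of AMP-activated kinase, fell from 87.7 ± 26.2 to 13.9 ± 11 CPM (-2.64 ± 0.58). In total 44 of 30890 genes passed edgeR's test, 40 higher and 4 lower, against 158 by DESeq2 and 11 with only the libraries compared. The other 3 falls, named here after their values were seen, were in Krt18 (-7.53 ± 1.5), Dhrs13 (-5.98 ± 1.39) and Gm3375 (-4.62 ± 0.94). Members of the Krt6, Stfa and Lce families have close copies, so reads shared between copies make the split within a family uncertain.

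The list of hyperproliferative keratinocyte genes rose at 10 weeks (adjusted p = 4.61e-16), 11 of 24 members over the list alone and 5 over all genes, among them Sprr1b, a cornified envelope precursor (69.6 ± 61.7 against 0.831 ± 1.06 CPM), and the gap junction gene Gjb2 (31.3 ± 17.3 against 0.796 ± 1.13 CPM). Epidermal differentiation genes rose as well (adjusted p = 9.58e-15), 13 of 29 members with 1 lower over the list alone and 3 over all genes. Lce1g had 22.9 ± 10.7 against 1.29 ± 1.42 CPM and Hrnr 57.1 ± 23.9 against 13.4 ± 7.90 CPM. Both calls hold with an estimated correlation (adjusted p = 0.0173 for each). Alarmins and IL-17 response genes rose (adjusted p = 7.41e-14, and adjusted p = 0.0214 with an estimated correlation), 10 of 20 members over the list alone and 2 over all genes. The antimicrobial peptide Defb14 had 7.70 ± 5.56 CPM in the knockout and 0 counts in control skin, at least 28.1-fold higher, and the chemokine Cxcl3 9.35 ± 8.83 against 0.241 ± 0.539 CPM. S100a8 had 236 ± 220 against 23.1 ± 36.9 CPM (adjusted p = 0.466) and Il1b 184 ± 228 against 7.72 ± 6.45 CPM (adjusted p = 0.103). Neutrophil genes rose as a list (adjusted p = 1.77e-10, and adjusted p = 0.165 with an estimated correlation; 9 of 21 over the list alone), and skeletal muscle genes fell as a list (adjusted p = 1.45e-11, and adjusted p = 0.23 with an estimated correlation; 0 of 22 over the list alone). Actn3 had 1020 ± 621 against 2370 ± 653 CPM. Interferon response genes rose as a list (adjusted p = 1.45e-09, and adjusted p = 0.0568 with an estimated correlation; 1 of 32 over the list alone). So did hair shaft and inner root sheath genes (adjusted p = 0.0104, and adjusted p = 0.81 with an estimated correlation; 2 of 30 over the list alone), a call that ended without control library b (0.0858) or knockout replicate 2 (median log2 -0.46, adjusted p = 0.589). Cartilage genes, which ear tissue holds in bulk, did not pass as a list (adjusted p = 0.201, 7 of 17 members higher over the list alone). Acan had 124 ± 170 against 7.65 ± 13.6 CPM and Col2a1 96.4 and 73.4 CPM in knockout libraries a and b and at most 12 CPM in the other 8. With libraries a and b of each genotype only, the neutrophil median changed sign (log2 -0.34, adjusted p = 0.995), the hair call ended (0.12, 0.774), the interferon call ended (0.165) and the cartilage list rose (4.23, 2.01e-19), and it was also called without control replicate 1 (0.0403), knockout replicate 1 (0.0129) or 2 (0.0114). Libraries a and b and replicates 1 to 3 are 2 sets present in both genotypes, which the model of 5 against 5 ignores. With the set as a covariate the cartilage list was called (median 0.38, adjusted p = 8.38e-07) and 52 genes passed, 41 of them among the 44.

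Leaving out libraries of 10-week skin moved the count of 44 to 27, 13 and 12 without control replicates 1, 2 and 3, and to 21 without knockout library a or b. Without the shallow or high-background libraries, a set chosen after seeing the data that includes both, 8 genes passed. Wdr46, Casp14 and Aqp3 were the 3 of 11 named genes that kept their call without each library in turn. Without the shallow or high-background libraries Aqp3 lost it (1.82, adjusted p = 0.0771), as did Krt6b, Krt16 and Krt6a. Wdr46 (2.93, 0.181) and Casp14 (2.5, 0.0562) lost it with only the libraries compared. All 11 lost it with libraries a and b only.

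**Figure D3:**
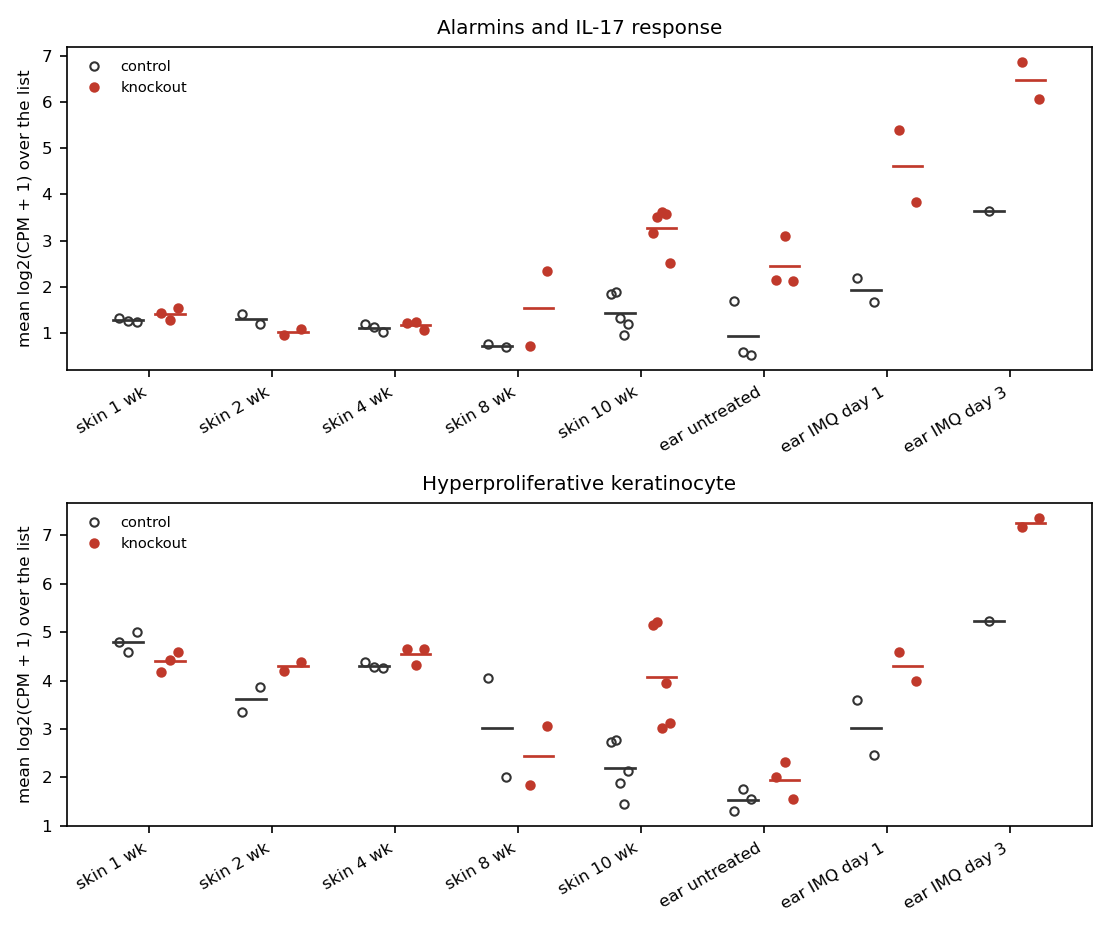
Mean log2(CPM + 1) over the alarmin and IL-17 response list (top) and the hyperproliferative keratinocyte list (bottom) in whole skin and ear, with 1 point per library and a line at the group mean for each genotype. The control ear library of 4059 counts on day 3 is not drawn, and knockout means lie above control means in 10-week skin and on both days of imiquimod.

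Averaged over the 5 ages with equal weight, no gene of 30890 passed edgeR's test (2378 at an unadjusted p under 0.05, 87 by DESeq2). The smallest p-values belonged to Sfn, a keratinocyte 14-3-3 protein (log2 1.01 ± 0.24), Rnf213 (1.37 ± 0.33), Nek6 (1.88 ± 0.47), Tmem52 (-1.11 ± 0.26), Wfdc3 (-1.41 ± 0.33) and Hhatl (-1.14 ± 0.27), at adjusted p of 0.377 to 0.448. Skeletal muscle genes fell as a list (adjusted p = 4.75e-14, and adjusted p = 0.236 with an estimated correlation), 12 of 22 over the list alone. Pvalb had -1.29 ± 0.37. The muscle call ended without shallow or high-background libraries (median log2 -0.04). That fit left out 2 weeks, where the muscle list had a median of -2.59. Interferon response genes rose as a list (adjusted p = 2.55e-05, and adjusted p = 0.236 with an estimated correlation; 0 of 32 over the list alone). Zbp1 had 2.41 ± 0.75. The interferon call ended without 2-week knockout library b (0.0848), where its median turned from 0.43 to -0.75. It also ended without 8-week knockout library a (0.351). The count became 29, 2 and 1 without 8-week knockout library a, 8-week control library a and 10-week knockout replicate 2.

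A test of genotype by age asked which genes differ between genotypes by an amount that depends on age, and 21 of 30890 passed edgeR's test (397 by DESeq2, 9 without shallow or high-background libraries). Casp14 led it (adjusted p = 0.0117), with log2 changes of -0.50 ± 0.48, -0.65 ± 0.66, 0.66 ± 0.48, -1.34 ± 0.63 and 2.54 ± 0.41 at 1, 2, 4, 8 and 10 weeks. Sprr1b (adjusted p = 0.0307) went from -1.63 ± 0.89 at 1 week to 6.26 ± 0.94 at 10 weeks, and Hrnr (0.0307) from -0.67 ± 0.54 to 2.09 ± 0.45. Gjb2 (adjusted p = 0.0252) had -8.76 ± 1.93 at 8 weeks and 5.54 ± 1.04 at 10 weeks, and Gcat (0.0233) -3.57 ± 0.68 and 0.47 ± 0.39. The count was 7, 60 and 33 without 8-week control libraries a and b and knockout library a. It was 10 to 13 without some single libraries of 1, 4 and 10 weeks. Casp14 alone of the 10 named genes kept its call without each library. Without shallow or high-background libraries Casp14, Sprr1b and Ogfod3 were still called and the other 7 were not.

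Control skin itself changed with age, giving the background for those comparisons. Of 30890 genes 7919 differed between the 5 ages, led by genes of striated muscle: Mb (myoglobin, adjusted p = 2.32e-18), Myh2, Xirp2, Ryr1 and Obscn. Between 1 week (n = 3) and 10 weeks (n = 5) the fast myosin Myh4 rose from 3.77 ± 1.77 to 16000 ± 6170 CPM (log2 12.04 ± 1.21) and Pvalb from 1.95 ± 1.03 to 6470 ± 3490 CPM (11.67 ± 1.14), with Sbk2 (9.39 ± 1.64), Mylk4 (8.82 ± 1.12) and Cyp2e1 (8.66 ± 1.38) next. Inner root sheath and hair keratins fell, Krt25 from 5720 ± 470 to 0.859 ± 1.19 CPM (-12.88 ± 2.39) and Krt71 from 10100 ± 3230 to 1.75 ± 3.26 CPM (-12.35 ± 2.08). Krt27, Krt73 and Krtap16-3 went from 4570 ± 877, 1190 ± 326 and 553 ± 116 CPM to 0.328 ± 0.526, 0.174 ± 0.389 and 0.241 ± 0.539 CPM. In that contrast 3577 genes were higher and 2421 lower at 10 weeks, against 5725 and 1549 with DESeq2 size factors, and the median log2 change of all genes was 1.41 and 1.96. Skeletal muscle genes rose (21 of 22 over all genes, 22 over the list alone, adjusted p = 8.85e-17, and adjusted p = 0.0949 with an estimated correlation) and hair shaft genes fell (29 of 30 over all genes and over the list alone, adjusted p = 6.49e-18, and adjusted p = 0.0949 with an estimated correlation). Epidermal differentiation (24 of 29 lower over all genes, 1 higher; 24 and 2 over the list alone), proliferation (24 of 27, 25 over the list alone) and melanocyte genes (7 of 12, 8 over the list alone) fell, and these 3 calls hold with an estimated correlation (adjusted p = 0.00192, 0.00192 and 0.00659). Hmgb2 had 15.2 ± 9.01 against 259 ± 32.4 CPM and Pmel 12.7 ± 11 against 957 ± 217 CPM. Without single 1-week or 4-week replicates the count over ages was 4387 to 5054. The contrast's 5998 became 2235 to 2416 without 1-week replicates. All named genes kept their calls.

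In untreated ear, the starting state for the imiquimod series (n = 3 per genotype), Pck1, the rate-limiting enzyme of gluconeogenesis and of glycerol synthesis in fat, rose from 1.60 ± 0.789 to 48.4 ± 18.1 CPM (log2 4.88 ± 0.90, adjusted p = 0.00498). Klhdc10 rose from 15.6 ± 11 to 90.8 ± 69.6 CPM (2.54 ± 0.56, adjusted p = 0.0429) and the heparan sulfatase Sulf2 from 9.45 ± 7.51 to 53.1 ± 27.1 CPM (2.47 ± 0.55, adjusted p = 0.0424). In total 18 of 30890 genes passed edgeR's test, 16 higher and 2 lower, against 385 by DESeq2. For comparison, 2 other splits of these 6 libraries gave 35 and 23. The 2 lower, named after their values were seen, were Cd300lg (-4.68 ± 0.97) and Sardh (-4.52 ± 0.88). Neutrophil genes rose as a list (adjusted p = 3.07e-07, and adjusted p = 0.634 with an estimated correlation; 7 of 21 over the list alone, 0 over all genes). Clec4d had 28.0 ± 26.9 CPM against 0 counts, at least 62.8-fold higher, and Cxcl2 65.8 ± 61.1 CPM against 0 counts, at least 148-fold higher. Alarmin and IL-17 response genes rose as a list (adjusted p = 0.000609, and adjusted p = 0.715 with an estimated correlation; 3 of 20 over the list alone). Il1b had 104 ± 81.1 against 1.36 ± 2.01 CPM. S100a8 had 104 ± 99.5 against 56.4 ± 97.6 CPM. Adipocyte genes rose as a list (adjusted p = 1.5e-05, and adjusted p = 0.476 with an estimated correlation; 1 of 17, Pck1, over the list alone and over all genes). Erythroid genes, markers of blood, were lower (adjusted p = 0.00382, and adjusted p = 0.715 with an estimated correlation; 7 of 8 over the list alone). Hbb-bs had 133 ± 64.7 against 1830 ± 3020 CPM. That call rests on control replicate 1, without which the median changed sign (log2 0.46, adjusted p = 0.58), and it ended without knockout replicate 3 (0.13). The count of 18 became 29 without control replicate 2 and 10 and 11 without knockout replicates 2 and 3, and Pck1 kept its call without each library but lost it with only the libraries compared (4.85, adjusted p = 0.152), which left 0 genes.

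On day 1 of imiquimod (n = 2 per genotype) Alox12e, an epidermal lipoxygenase, was the only gene of 30890 to pass edgeR's test between genotypes, from 43.4 ± 23.0 CPM in control to 2.91 ± 0.754 CPM in knockout ear (log2 -3.87 ± 0.73, adjusted p = 0.0417). By DESeq2 65 genes passed, Alox12e among them, and with only the libraries compared 0. Alarmin and IL-17 response genes were higher in the knockout as a list (adjusted p = 2.66e-32, and adjusted p = 0.000354 with an estimated correlation), 7 of 20 members over the list alone and 0 over all genes. S100a8 had 897 ± 716 against 20.3 ± 1.35 CPM and Cxcl2 465 ± 563 against 2.21 ± 0.818 CPM. Neutrophil genes (adjusted p = 1.97e-27, and adjusted p = 0.00971 with an estimated correlation; 10 of 21 over the list alone) and hyperproliferative keratinocyte genes (adjusted p = 1.11e-19, and adjusted p = 0.00523 with an estimated correlation; 1 of 24 over the list alone) were higher too. Clec4d had 154 ± 194 against 1.92 ± 0.747 CPM and Sprr2d 29.5 ± 7.60 against 0.808 ± 0.0141 CPM. Genes of tissue dissociation stress, which sample handling also induces, were higher (adjusted p = 1.95e-17, and adjusted p = 0.00025 with an estimated correlation; 6 of 20 over the list alone). Fos had 116 ± 78.3 against 16.1 ± 2.00 CPM. Basal keratinocyte genes were lower (adjusted p = 9.24e-10, and adjusted p = 0.0406 with an estimated correlation; 3 of 13 over the list alone). Krt15 had 516 ± 62.5 against 1830 ± 102 CPM. Alox12e was no longer called without control replicate 1 (-3.24, adjusted p = 1), a high-background library, or knockout replicates 1 (-3.58, 1) or 2 (-3.97, 0.98), each of which left 0 genes. Without control replicate 2, 3 genes passed.

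On day 3 (n = 1 control and 2 knockout) Krt77, a keratin of sweat ducts and differentiating epidermis, was the only gene of 30890 to pass edgeR's test between genotypes, with 4.17 ± 1.45 CPM in knockout and 115 CPM in control ear (log2 -4.76 ± 0.86, adjusted p = 0.0241). By DESeq2 79 genes passed, and with only the libraries compared 44 (35 higher and 9 lower), each set with Krt77. It was not called without shallow or high-background libraries (-4.83, adjusted p = 0.0631). Alarmin and IL-17 response genes were higher in the knockout as a list (adjusted p = 1.28e-34, and adjusted p = 0.00023 with an estimated correlation; 1 of 20 over the list alone). Il1b had 2750 ± 1300 against 56.9 CPM, S100a8 8130 ± 1110 against 695 CPM and Il23a 7.33 ± 1.79 CPM against 0 counts. Neutrophil genes (adjusted p = 1.32e-47, and adjusted p = 0.000491 with an estimated correlation; 0 of 21 over the list alone) and hyperproliferative keratinocyte genes (adjusted p = 5.9e-36, and adjusted p = 0.00023 with an estimated correlation; 0 of 24 over the list alone) were higher. Csf3r had 124 ± 112 CPM against 0 counts, at least 205-fold higher, and Krt6a 3790 ± 589 against 547 CPM. Adipocyte genes were lower (adjusted p = 5.43e-15, and adjusted p = 0.00628 with an estimated correlation; 0 of 17 over the list alone). Cd36 had 75.9 ± 9.31 against 185 CPM. The adipocyte list was not called with fry. The single control sample is assumed to vary like the other groups, and Krt77 was not called without knockout replicate 1 (-4.43, adjusted p = 1) or 2 (-5.35, adjusted p = 1).

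Imiquimod itself was followed within each genotype against untreated ear. On day 1 in control ear (n = 2 against 3) 11 of 30890 genes rose by edgeR (144 changed by DESeq2 and 0 with only the libraries compared), among them Aqp3 from 31.5 ± 10.6 to 236 ± 131 CPM (log2 2.90 ± 0.60, adjusted p = 0.0431). Interferon response genes rose as a list (adjusted p = 1.04e-23, and adjusted p = 0.00394 with an estimated correlation), 8 of 32 over the list alone. Ifit1 had 47.3 ± 42.6 CPM against 0 counts, at least 106-fold higher. Hyperproliferative keratinocyte genes rose (adjusted p = 0.000292, and adjusted p = 0.49 with an estimated correlation; 7 of 24 over the list alone). Krt16 had 75.4 ± 2.03 against 1.67 ± 2.45 CPM. The count was 6 and 2 without day 1 replicates 1 and 2, and 21, 17 and 3 without untreated replicates 1, 2 and 3, and Aqp3 was not called without day 1 replicate 1 (2.31, adjusted p = 0.373) or 2 (3.27, 0.0509), or untreated replicate 1 (2.7, 0.119) or 3 (2.72, 0.159).

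By day 3 in control ear (1 sample against 3) 70 genes rose and 0 of 30890 fell, against 1930 at an unadjusted p under 0.05. By DESeq2 165 rose and 248 fell, and with only the libraries compared 47 and 57, so the absence of falls depends on the fit. The 70 were led by products of differentiating epidermis. Klk8, a kallikrein protease, rose from 4.79 ± 2.93 to 187 CPM (log2 5.25 ± 0.74, adjusted p = 2.16e-05), and Calm4 from 181 ± 17.7 to 3200 CPM (4.15 ± 0.92). Next came Casp14 (4.33 ± 0.66), the defensin Defb6 (3.99 ± 0.75), Csta1 (3.74 ± 0.75), Krt6a (3.71 ± 0.79), Krt1 (3.70 ± 0.66), Krt78 (3.66 ± 0.76), Lce1i (3.63 ± 0.79) and Hrnr (3.56 ± 0.71). Epidermal differentiation genes rose (8 of 29 over all genes, 21 over the list alone, adjusted p = 3.31e-35), as did hyperproliferative keratinocyte genes (9 of 24, 15 over the list alone, adjusted p = 1.84e-29) and proliferation genes (0 of 27, 12 over the list alone, adjusted p = 4.52e-20), and these calls hold with an estimated correlation (adjusted p = 0.000226, 0.00063 and 0.00236). Krt16 had 864 against 1.67 ± 2.45 CPM and Mki67 142 against 35.1 ± 28.3 CPM. Alarmin genes rose (1 of 20, 5 over the list alone, adjusted p = 4.39e-12, and adjusted p = 0.043 with an estimated correlation). Stfa1 had 78.8 CPM against 0 counts, at least 177-fold higher. Cartilage genes, a marker of how much ear cartilage the sample held, fell as a list (0 of 17 over the list alone, adjusted p = 2.95e-09, and adjusted p = 0.082 with an estimated correlation). Sox9 had 73.3 against 295 ± 49.0 CPM. Without untreated replicate 3 the count was 40, and Klk8, Casp14, Defb6, Krt1 and Hrnr kept their call without each library.

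In knockout ear 37 genes changed on day 1 (n = 2 against 3), 22 higher and 15 lower, against 22 and 35 with DESeq2 size factors and 279 and 482 by DESeq2. Ifit3 and Bst2, both induced by interferon, rose from 3.74 ± 3.4 to 84.1 ± 28.9 CPM (log2 4.54 ± 1.01) and from 6.66 ± 1.42 to 128 ± 57.2 CPM (4.25 ± 0.72), followed by Krt6a (3.76 ± 0.72) and the muscle genes Xirp1 (3.62 ± 0.73) and Mustn1 (3.17 ± 0.70). The fat droplet protein Plin1 fell from 102 ± 76.8 to 1.29 ± 1.82 CPM (-6.29 ± 1.18), with Fndc1 (-5.15 ± 0.94), Fa2h (-5.05 ± 0.89), Aoc3 (-4.41 ± 0.89) and Dhcr24 (-4.16 ± 0.92) next. Interferon response genes (3 of 32 over all genes, 18 over the list alone, adjusted p = 7.74e-33) and alarmin genes (1 of 20, 5 over the list alone, adjusted p = 1.64e-17) rose and adipocyte genes fell (2 of 17, 9 over the list alone, adjusted p = 3.82e-14), and the 3 calls hold with an estimated correlation (adjusted p = 0.000405, 0.0077 and 0.0077). Without untreated replicates 1, 2 and 3 the count was 24, 22 and 8. Of the 20 named genes 0 kept their call without each library.

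On day 3 in knockout ear (n = 2 against 3) 262 genes changed, 223 higher and 39 lower, against 147 and 86 with DESeq2 size factors and 513 and 619 by DESeq2. Krt6b rose from 1.80 ± 2.88 to 2760 ± 482 CPM (log2 10.92 ± 1.53), Saa3, an acute phase protein, from 0.648 ± 0.928 to 440 ± 90.5 CPM (9.22 ± 1.68), and Sprr1b (9.03 ± 1.28), Stfa1 (9 ± 1.24) and Sprr2d (8.82 ± 1.14) followed. Irs1, an insulin signalling adaptor, fell from 71.2 ± 53.4 to 1.26 ± 0.973 CPM (-5.74 ± 1.37), with Nbea (-4.06 ± 1.05), Paqr7 (-4.04 ± 0.79), Eef1a2 (-3.93 ± 0.89) and Col4a6 (-3.51 ± 0.90). Hyperproliferative keratinocyte genes (14 of 24 over all genes, 21 over the list alone, adjusted p = 2.93e-51), alarmin and IL-17 response genes (2 of 20, 17 over the list alone, adjusted p = 4.12e-41) and neutrophil genes (1 of 21, 16 over the list alone, adjusted p = 3.9e-35) rose. S100a8 had 8130 ± 1110 against 104 ± 99.5 CPM. Proliferation genes rose (2 of 27, 12 over the list alone, adjusted p = 1.68e-17, and adjusted p = 0.00285 with an estimated correlation). Epidermal differentiation genes rose (7 of 29 with 1 lower, 16 with 2 lower over the list alone, adjusted p = 7.72e-18), adipocyte genes fell (0 of 17, 10 over the list alone, adjusted p = 1.11e-13) and cartilage genes fell (0 of 17 over the list alone, adjusted p = 1.84e-12). The other 6 calls hold with an estimated correlation (adjusted p = 2.42e-05, 5.92e-05, 0.00257, 0.00337, 0.00538 and 0.0257). Without untreated replicates 1, 2 and 3 the count was 180, 126 and 67.

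The interaction of genotype and imiquimod tested whether the response itself differed. The percent of Ndufs5 in its joint counts with Ndufs5-ps separated the genotypes in treated but not in untreated ear. A strain difference between these mice therefore cannot be told apart from an effect of the knockout here. On day 1, 2 of 30890 genes passed edgeR's test (160 by DESeq2 and 0 with only the libraries compared), Pck1 with a response lower by 7.28 ± 1.36 on the log2 scale in the knockout (adjusted p = 0.0145) and, named after its values were seen, Fcho1 (-11.10 ± 2.04). Adipocyte genes responded lower as a list in the knockout on day 1 (adjusted p = 4.1e-05, and adjusted p = 0.265 with an estimated correlation; 1 of 17, Pck1, over all genes and over the list alone). Alarmin and IL-17 response genes responded higher (adjusted p = 4.57e-05, and adjusted p = 0.338 with an estimated correlation; 0 of 20 over the list alone), a call that ended without day 1 knockout replicate 1 (0.0585). Without untreated control replicate 1 its median fell from 2.22 to -0.02, although the list was still called (0.00473). On day 3 no gene passed edgeR's test (1028 at an unadjusted p under 0.05, 78 by DESeq2), and Dusp1 (3.80 ± 1.04), Il4ra (4.15 ± 1.23), Btg2 (3.64 ± 1.10), Pck1 (-6.46 ± 1.38, adjusted p = 0.379), Bora (-5.48 ± 1.34) and Krt77 (-3.96 ± 1.01) had the smallest p. Adipocyte genes responded lower on day 3 (adjusted p = 6.09e-18, and adjusted p = 0.00627 with an estimated correlation; 1 of 17 over the list alone). The alarmin list did not pass (adjusted p = 0.0577; 0 of 20 over the list alone, and adjusted p = 0.849 with an estimated correlation) but did without day 3 knockout replicate 2 (0.0192), untreated control replicate 2 (0.0213) or 3 (0.0258) or untreated knockout replicate 2 (0.00635). It was also called with the 2 day 3 control libraries kept apart (median log2 1.81, adjusted p = 7.92e-05), without shallow or high-background libraries (1.62, 0.0159) and with DESeq2 size factors (0.0498), but not with only the libraries compared (0.142), so whether it passes depends on the setting and on single libraries. Its median fell from 1.69 to -0.01 without untreated control replicate 1. The day 1 count became 0 without day 1 control replicate 1 or knockout replicate 2, 1 without day 1 knockout replicate 1 or untreated knockout replicate 1 or 2, and 8, 10 and 5 without untreated control replicates 1, 2 and 3. Pck1 was not called without day 1 control replicate 1 (adjusted p = 0.118), day 1 knockout replicate 1 (0.938) or 2 (0.339), or untreated knockout replicate 2 (0.0667).

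Il17a had at most 8 counts in any group of whole skin or ear and Foxp3 at most 18, so a difference in either was not detectable at this depth in whole tissue. Trdc had 1.05 ± 1.11 CPM in knockout and 11 ± 7.80 CPM in control skin at 10 weeks (adjusted p = 0.466), and 1.01 ± 1.75 and 20.8 ± 9.54 CPM in untreated ear (adjusted p = 0.4).

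**Figure D4:**
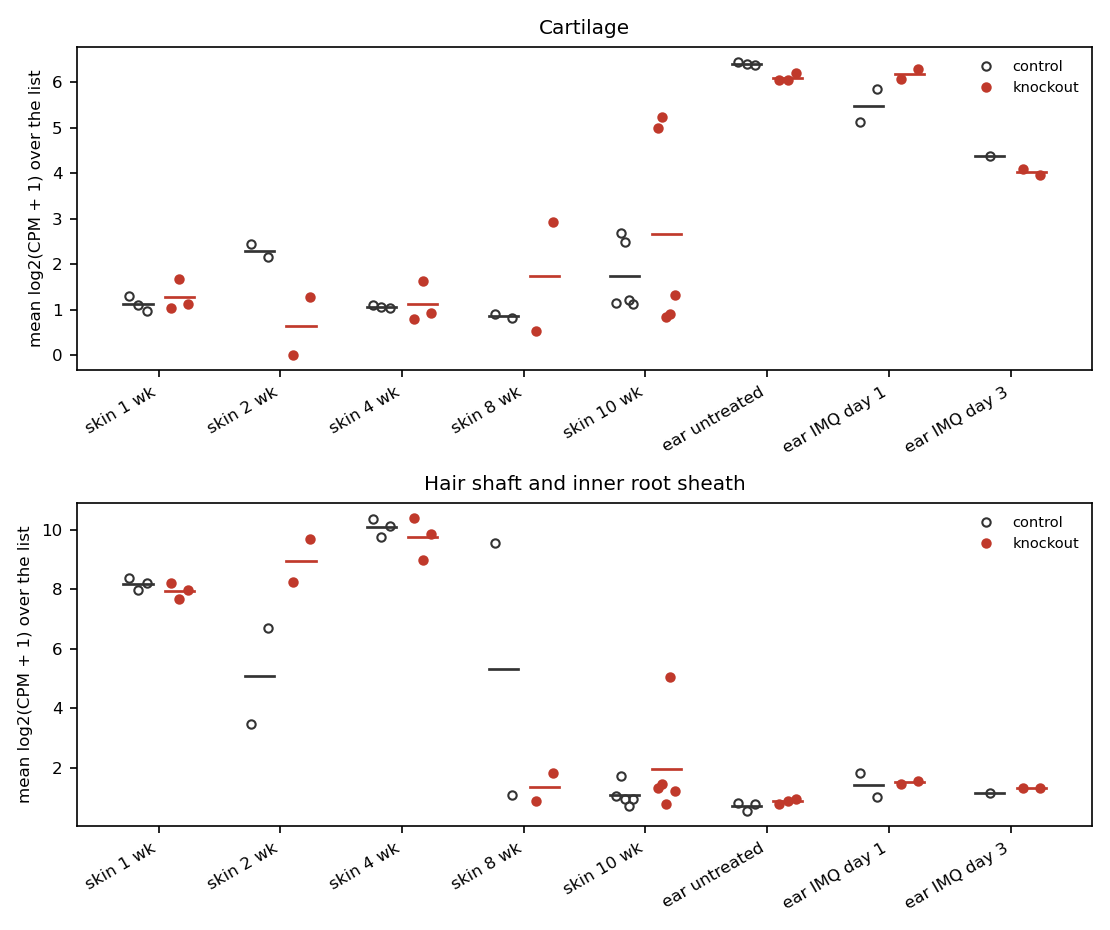
Mean log2(CPM + 1) over the cartilage list (top) and the hair shaft and inner root sheath list (bottom) in whole skin and ear, with 1 point per library and a line at the group mean for each genotype. Without the control ear library of 4059 counts. Knockout libraries a and b of 10-week skin sit at 4.99 and 5.23 on the cartilage list, the other 10-week skin libraries at 0.84 to 2.68 and untreated ear at 6.04 to 6.45.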

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

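The results here have 1 library far from the others of its group, or differ between ages or between treated and untreated ear by a test of the difference itself. The tests against ear tissue, against the library high in hair genes and against shallow or high-background libraries were chosen after the result was seen, and the test of hair stage and the comparison with ear libraries before.

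Among the 5 knockout skin libraries at 10 weeks, replicate 2 stood far above the others on the hair shaft and inner root sheath list (mean log2(CPM + 1) of 5.04, nearest other 1.44). Replicate 3 stood below the others on the interferon response list (2.59, nearest other 3.85). These came from 2 of 38 tests for such a library, both in the same group, and chance gives about 1 in 20.

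For 10 named genes the test of genotype by age passed. Casp14 (adjusted p = 0.0117), Gjb2 (0.0252), Hrnr (0.0307) and Sprr1b (0.0307), all of the epidermis, were higher in knockout skin at 10 weeks. Gcat (adjusted p = 0.0233) and Foxn1 (0.0307) were lowest in the knockout at 8 weeks, with log2 changes of -3.57 ± 0.68 and -4.84 ± 1.14. Ank2 (adjusted p = 0.0307, log2 4.99 ± 0.96), Ogfod3 (0.0371, 6.78 ± 1.37) and Adprhl1 (0.0378, 4.79 ± 1.12) were highest at 8 weeks, where n = 2 per genotype. Rcan2 (adjusted p = 0.0307) had log2 changes of 2.23 ± 0.68 at 1 week and 3.67 ± 0.75 at 4 weeks. Without shallow or high-background libraries 7 of the 10 lost the call: Gcat (0.773), Gjb2 (0.21), Ank2 (1), Hrnr (1), Rcan2 (1), Foxn1 (0.607) and Adprhl1 (0.825). The block, which lacks 2 and 8 weeks, cannot test Foxn1, Gcat, Ogfod3, Ank2 and Adprhl1 at 8 weeks. With it Casp14 (0.0927), Hrnr (0.0706) and Rcan2 (0.294) lost the call. With DESeq2 size factors Sprr1b (0.0573) lost it. All but Casp14 lost it without some library, so each of the 10 lost it in some setting.

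The higher keratin and alarmin transcripts of knockout skin at 10 weeks were weighed against 3 technical explanations, the first because knockout libraries a and b (2 of 2) correlate better with untreated ear than with the other 10-week knockout skin over 638 list genes (r = 0.881 against 0.851 and 0.903 against 0.883), so these 2 may hold ear tissue. With replicates 1 to 3 only, the alarmin list still had a median log2 change of 3.74 (adjusted p = 8.73e-09) and the hyperproliferative keratinocyte list 1.86 (adjusted p = 4.8e-09), and without shallow or high-background libraries 3.35 (adjusted p = 1.21e-06) and 1.86 (adjusted p = 3.97e-06), which neither ear tissue in those 2 libraries nor low depth predicts for these lists. Single keratins lost their call without shallow or high-background libraries, with fewer samples and wider errors, as Krt6b went from 4.92 ± 0.91 to 4.77 ± 1.10 (adjusted p = 0.228), Krt16 from 4.09 ± 0.80 to 3.31 ± 0.84 (0.268) and Krt6a from 2.56 ± 0.51 to 2.09 ± 0.64 (0.393), and with replicates 1 to 3 only Krt16 did too (4.62 ± 1.00, 0.0514). The hair list was higher in replicates 1 to 3 as well (median 4.13, adjusted p = 0.00313), but it is not called without knockout replicate 2 (-0.46, adjusted p = 0.589) while the alarmin list still is (median 2.92), so hair stage in that 1 library does not account for the alarmins and an effect of the knockout stays open. Sample handling was not tested and stays open. Dissociation stress list means were 5.65 to 5.84 in knockout and 4.84 to 5.31 in control libraries. For the count of genes, the real split gave 44 and the highest of the 24 others 11 (1 of 25 splits as large).

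The response to imiquimod on day 1 differed between genotypes for Pck1 (adjusted p = 0.0145), for the alarmin and IL-17 response list (adjusted p = 4.57e-05) and for the adipocyte list (adjusted p = 4.1e-05). On day 3 it differed for the adipocyte list (adjusted p = 6.09e-18), which holds with an estimated correlation (0.00627). Neither day 1 list is called with an estimated correlation (adjusted p = 0.338 for alarmins and 0.265 for adipocytes). The alarmin and Pck1 calls also ended without single libraries, as given above, so these day 1 differences are not settled.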

How the results depend on the processing

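Counts of genes move with tool and filter. Most named genes keep their direction, but the naming rule favours this, so it is no support. Of the named genes, 161 kept their side of the threshold under DESeq2 and 26 were added. With its size factors 177 kept it and 10 lost it. Of the 73 reported lists that were called, a selection, 30 kept their call with fry and 35 with an estimated correlation. Of all lists called, 0 kept it with the latter in genotype comparisons of sorted cells, skin at 4 and 8 weeks, untreated ear and the mean over ages. Elsewhere at most 10 per comparison did. A minimum of 2-fold left all 22 counts within 1.5 times, but counts of 0 and tests over several groups could not change. The cause of the changes below was not tested, apart from the smaller number of samples where libraries are left out.

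Counts by DESeq2 were 165 for spleen Treg, 158 for Tcon, 192 for γδ T, 13, 145, 22, 1564 and 158 for skin at 1, 2, 4, 8 and 10 weeks, 385, 65 and 79 for ear untreated and on days 1 and 3, 87 for the mean over ages, 397 for genotype by age, 144 and 413 for imiquimod in control ear, 761 and 1132 in knockout ear, and 160 and 78 for the interactions. Without the filter, in the same order, they were 256, 215, 116, 1, 15, 10, 112, 119, 103, 17 (day 1), 30, 264, 59, 167, 172, 408, 32 and 3. With DESeq2 size factors they were 58 for skin at 8 weeks, 2 for the genotypes on day 1, 3 and 34 for imiquimod in control ear and 57 on day 1 in knockout ear, and the median log2 change of all genes shifted by -0.33 at 2 weeks, 0.71 at 8 weeks, -0.11 at 10 weeks, -0.12 and -0.32 for imiquimod in control ear, -0.19 and -0.30 in knockout ear and 0.53 between 1 and 10 weeks.

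With only the libraries compared, counts were 2, 637, 0 and 11 for skin at 1, 2, 8 and 10 weeks, 0, 0 and 44 for ear untreated and on days 1 and 3, 0 for day 1 in control ear, 236 and 554 in knockout ear and 0 for the day 1 interaction. Without shallow or high-background libraries they were 1, 0 and 8 for skin at 4, 8 and 10 weeks, 0 and 0 for the genotypes on days 1 and 3, 9 for genotype by age, 117 for day 3 in control ear, 262 and 507 in knockout ear and 0 for the day 1 interaction.

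Samples that share a replicate number were not shown to be pairs: all pairs of a comparison correlated above 0.1 only between 1-week and 4-week control skin (0.157 to 0.333). With the number as a block the counts were 22 for spleen Treg, 45 for γδ T, 1 for skin at 1 week, 0 for untreated ear (Pck1 4.84, adjusted p = 0.505), 23 for the genotypes on day 1, 1 for the mean over ages, 281 and 707 in knockout ear and 31 and 199 for the interactions, and Izumo1r in Tcon cells had -2.46 (adjusted p = 0.0528).

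Leaving out 1 replicate gave 20 to 171 genes for spleen Treg (Izumo1r -2.60 to -2.50), 0 to 22 for Tcon (Izumo1r -2.73 to -2.27), 0 to 1528 for γδ T, 0 to 0, 0 to 5, 0 to 1, 0 to 610 and 12 to 65 for skin at 1, 2, 4, 8 and 10 weeks, 10 to 29, 0 to 3 and 0 to 0 for ear untreated and on days 1 and 3, 0 to 29 for the mean over ages, 7 to 60 for genotype by age, 2 to 21 and 40 to 77 for imiquimod in control ear, 8 to 24 and 67 to 180 in knockout ear, 0 to 10 and 0 to 0 for the interactions, 4387 to 8989 for age, 2235 to 7849 between 1 and 10 weeks, and 749 to 1642 for γδ T against Tcon (Izumo1r -12.10 to -8.67).

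The median changed sign for the neutrophil list at 10 weeks with libraries a and b only (-0.34), the cartilage list at 10 weeks with the block (-1.47), with replicates 1 to 3 (-0.75) and without shallow or high-background libraries (-1.65), the hair list at 10 weeks without knockout replicate 2 (-0.46), the erythroid list in untreated ear without control replicate 1 (-4.77 to 0.46 without 1 library) and the interferon list averaged over ages without 2-week knockout library b (-0.75). For the alarmin list in the interactions it changed sign without untreated control replicate 1 (-0.02 on day 1 and -0.01 on day 3) and with the block on day 3 (-0.43), while the test kept its direction. The change of Nek6 averaged over ages turned negative with the block (-0.03) and without 2-week knockout library b (-0.13 to 1.97 without 1 library). In 4 more cases the median kept its sign and only the test relative to the other genes changed direction, none of them called. These are the hair list at 2 weeks without knockout library b (medians without 1 library 2.29 to 7.09), the hair list at 10 weeks with libraries a and b only (0.12), the cartilage list at 10 weeks with only the libraries compared (0.42) and the muscle list averaged over ages without shallow or high-background libraries (-0.04). The last of these left out 2 weeks.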

Other observations

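Some transcripts were present in some libraries and absent in others of the same tissue. At 1 week Skint9 had 33.3 to 55.5 CPM in the 3 control and 0 in the 3 knockout libraries. Skint3 had 3.66 to 4.29 CPM and 0. Skint1 was present in both (4.72 to 15.5 and 5.49 to 10.4 CPM). At 4 weeks Skint9 went the other way, at 0 in control and 8.89 to 34.9 CPM in knockout skin. Ndufs5 and its processed copy Ndufs5-ps split the same way at 4 weeks, with 5.4 to 7.3 percent of their joint counts on Ndufs5 in control and 91.5 to 100 percent in knockout skin. Sex differed within some groups. Xist was high and the Y-linked Ddx3y low in 1 library each of control (167 and 0.927 CPM) and knockout skin (269 and 1.97) at 1 week, control skin at 2 weeks (1020 and 0.403) and knockout skin at 4 weeks (520 and 0), and Xist lay below Ddx3y in the rest of those groups. Knockout library b at 2 weeks held both (1150 and 32.3 CPM). An effect of sex was not tested.

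Of the tests below, those of Izumo1r and Foxp3 in Tcon cells and of the Ndufs5 share were chosen after the values were seen, and those of clustering, of chromosome 9 and of the splits before.

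A strain variant that segregates among the mice may explain these transcripts: in 6 of 19 groups the Ndufs5 share differed by over 0.3 between libraries. The genes with the smallest p at 4 weeks were tested for clustering, and their 13 pairs within 1 Mb stood at percentile 96.79 of 10000 random sets, which leaves it undecided. Genes called in spleen Treg cells within 20 Mb of Izumo1r were 2.66 times the number expected but rest on 2 genes, so DNA flanking the targeted gene stays undecided too. No biological explanation was tested.

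The libraries sorted as Foxp3 reporter-negative Tcon cells held Foxp3 and Izumo1r transcripts. Izumo1r in knockout Tcon cells was 16.7 percent of control, against 16.9 percent in spleen Treg cells, so a candidate explanation is that these transcripts come from cells in which the Foxp3-driven recombinase had acted. Treg cells like those of the spleen would bring both transcripts in proportion, but control Tcon cells had 104 percent of the Foxp3 and 6.33 percent of the Izumo1r of spleen Treg cells, a ratio of 16.5, which speaks against such cells as the source. Skin Treg cells were not sequenced, so a skin Treg cell with less Izumo1r was not tested.

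Counts of genes were compared with those of other splits of the samples. Between 1 and 10 weeks the real split gave 5998 genes and the highest other 1886 (1 of 25 splits as large, the smallest share that the draws allow). No other split drawn called as many genes, but a share of this size does not exclude chance. The comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05, and comparisons with fewer than 3 libraries in a group were not split. Real and highest other were 73 and 2 for spleen Treg cells (1 split as large), 1 and 0 for Tcon cells (1), 1315 and 0 for γδ T against Tcon cells (1) and 18 and 35 for untreated ear (3, another with 23). Where the real count is 0 every split is as large by construction, so the comparison says nothing about chance: real and highest other were 0 and 4 for the mean over ages (25 of 25), 0 and 0 for skin at 1 week (10) and 0 and 1 at 4 weeks (10).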
